A study of Mus musculus with 2 samples.

How the data were processed

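Ptf1a is a basic helix-loop-helix transcription factor needed for the formation of the pancreas and, later, for the acinar cells that make digestive enzymes. Its binding to DNA was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in 266.6 cells, a mouse pancreatic line with features of acinar cells. Per the labels' protocols, cells at passage 26 were fixed with 1% formaldehyde for 10 min, chromatin was broken to between 100 and 500 bp, and DNA from 2 immunoprecipitations was pooled into 1 library after gel isolation of 100 to 400 bp fragments. Unselected chromatin of the same line made the input library. There was 1 library per group and no replicate, so every test on reads compares these 2 libraries and not conditions, and every interval covers counting error only. Amplified reads without molecular identifiers are not independent molecules, which makes such intervals too narrow.

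The authors deposited each library as counts of single reads placed on the genome, with 1 line and a value of 1 per read and no normalization. The build was mm9, per the submitters' processing notes. The aligner, its settings and any filter on reads are not given in the sources used here. Every placed read was 37 bp long, and several reads may share a position and strand. The authors also deposited 1 list of peaks for the ChIP library, with a signal value for each peak. Per the file headers these are spans of 100 bp on a track of Ptf1a peaks. The values are whole numbers from 20 to 396, and the peak caller, its threshold, its scale and its use of the input are not given in the sources used here. The value is called the authors' peak height below. Across peaks (which are not independent replicates) it followed the number of ChIP reads with distinct position and strand within 100 bp of the listed position, with a Spearman correlation of 0.95. With all ChIP reads in that window the correlation was 0.94.

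The ChIP library held 28502488 reads and the input library 27959618 reads. Repeated reads, those beyond the first at a position and strand, were 10.2% of ChIP reads and 3.29% of input reads. The strand shift that brought most plus-strand and minus-strand read starts together was 145 bp in the ChIP library and 155 bp in the input library, searched in steps of 5 bp. Each read's 5′ end was therefore moved 73 bp downstream. A read was assigned to a peak when that point lay in the deposited span of 100 bp. Read starts on the plus strand were densest 75 bp before the listed position and those on the minus strand 74 bp after it. The listed position thus lay at the centre of the read pile and the deposited span covered its downstream side. A window of 100 bp to each side was added as an alternative once this had been seen.

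For each peak the ChIP count was tested against the input count with an exact two-sided conditional binomial test. The expected ratio was that of reads outside all peaks, 0.971 ChIP reads per input read. The p-values were adjusted by the Benjamini-Hochberg method over all 30691 peaks, with a threshold of 0.05. Ratios over many peaks, and ratios of the 5 lowest peaks under an alternative setting, add 0.5 reads to each count. So do ratios of the 10 highest peaks against the input density of 10 kb. Other ratios of single peaks use the counts as they stand with an exact 95% interval, and a count of 0 input reads was set to a floor of 3 reads to give a lower bound. Shares of reads have Wilson 95% intervals. The peaks named are the 10 with the highest lower limit of that ratio interval and the 5 with the lowest ratio (0.5 reads added), a rule fixed with the tests and their alternatives before the data were examined. Groups of peaks named below were chosen after their values were seen.

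Peaks were joined into groups where neighbours lay within 12.5 kb. Their number was compared with 100 random placements of the same number of peaks per chromosome, drawn over 1 kb bins in proportion to their input reads, with bins above the 99th percentile set to it. Peaks per Mb refer to 1 kb bins with at least 1 read in either library. A scan of 200 bp bins over chromosomes 1 to 19 and X used reads with distinct position and strand and the same binomial test, one-sided. Passing bins within 500 bp were joined into regions.

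The per-peak test and the scan were tested on simulated data made from the real input densities, with 200 sites changed and all others unchanged. Among the 30691 simulated peaks, the test called 0 of 50 sites changed 4-fold, 13 of 50 changed 8-fold, 38 of 50 changed 16-fold and 49 of 50 changed 32-fold. It called 0 of 30491 unchanged sites. With so few changed sites the adjusted threshold was stricter than for the listed peaks, most of which passed, so these shares do not give the power of the test on the listed peaks. Among 278677 simulated bins of chromosome 19, the scan called 2 of 50 bins changed 4-fold, 18 changed 8-fold, 45 changed 16-fold and 50 changed 32-fold, and 0 unchanged bins. The simulated counts came from smoothed input densities, without repeated reads or a local excess of input. The absence of calls among unchanged sites and bins thus does not give the rate of false calls in the real libraries. Work was done in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

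Genes near the peaks, the share of peaks at promoters, the 12 gene lists fixed beforehand and the search for E-box motifs were not analysed here, because gene positions and sequence of mm9 were not used here and coordinates were not carried between builds. The genes that the rule for naming had set aside for mention are for this reason not reported. Positions are given on mm9 and counted from 1.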

Results

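Binding of Ptf1a was measured in 266.6 pancreatic cells, taken by the study as a stand-in for early pancreatic progenitors, so that bound sites could be set beside genes expressed in embryonic dorsal pancreatic buds with and without the factor. The data comprised 1 Ptf1a ChIP library of 28502488 placed reads, 1 input chromatin library of 27959618 placed reads and the authors' list of 30691 Ptf1a peaks. The buds' expression values were not analysed here. Depth was similar in both libraries, and neither had a replicate.

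The first comparison was of Ptf1a-bound DNA with input chromatin at the listed positions. ChIP reads were concentrated there in a narrow pile. The 30691 spans held 5.10% of all ChIP reads (Wilson 95% interval 5.09 to 5.11%) and 0.376% of all input reads (0.373 to 0.378%). The ChIP share was thus 13.6-fold that of the input (exact 95% interval 13.5 to 13.7). In a window of 100 bp to each side of the listed position, the shares were 9.98% and 0.750%. In the central 200 bp, ChIP reads, scaled to library depth as RPM, stood at 16.3 RPM per kb per peak, against 0.977 in the flanks 1.5 to 2 kb away, a 16.6-fold difference (16.6 to 16.7). For peaks with no listed neighbour within 3 kb, an alternative chosen after seeing the data, the flanks held 0.538 RPM per kb and the difference was 27.6-fold. Input reads were also denser at the same positions, at 1.23 against 0.715 RPM per kb in the flanks, a 1.72-fold difference (1.71 to 1.73).

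**Figure D1:**
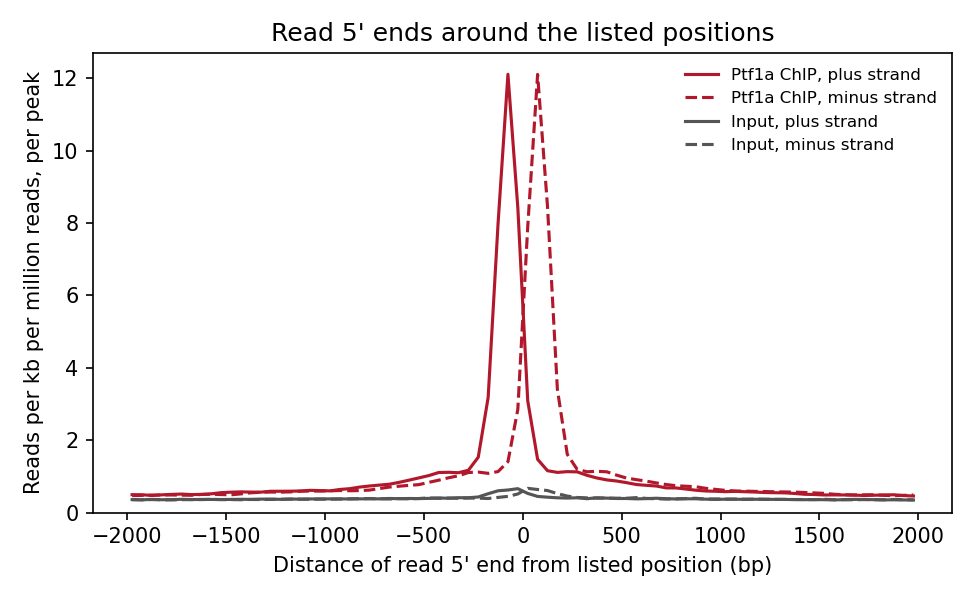
Mean density of read 5′ ends (RPM per kb per peak) in 50 bp bins up to 2 kb from the 30691 listed positions, for the plus strand (solid) and minus strand (dashed) of the ChIP and input libraries. ChIP read starts are densest 75 bp before the position on the plus strand and 74 bp after it on the minus strand, and the input rises far less at the same place.

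Mitochondrial DNA, which lies outside the nucleus, took a smaller share of the ChIP library than of the input library. It took 0.0205% of ChIP reads (0.0199 to 0.0210%) and 0.0512% of input reads (0.0504 to 0.0521%), so its share in the ChIP library was 0.399 times that in the input (0.387 to 0.412). Chromosome Y held 979 ChIP reads and 1007 input reads, and no listed peak.

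Tested one by one, 28112 of the 30691 listed sites (91.6%) had more ChIP than input reads, 71 had fewer, and 2508 did not pass the threshold (exact binomial test, Benjamini-Hochberg adjusted p under 0.05). The list was made for this same ChIP library and holds no height under 20, so an excess of ChIP reads was largely set by how the sites were chosen, and these p-values are not independent evidence of binding. The median site held 25 ChIP reads and 2 input reads in its span. The median ratio of ChIP to input was 10.9, with quartiles of 5.44 and 26.6. With the 3775 sites that had no input read set against 3 reads, the median was 10.8. With the window of 100 bp to each side, 30064 sites had more ChIP than input reads.

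The highest sites held much of the ChIP signal. The authors' peak heights ran from 20 to 396 with a median of 36. Heights of 20 to 29 made up 37.8% of the list (11615 peaks), and heights of 100 or more made up 13.3% (4090 peaks). The 3096 highest peaks held 41.1% of the ChIP reads found within 100 bp of listed positions. The median ratio of ChIP to input rose from 5.84 at heights of 20 to 29 to 9.68 at 30 to 49, 18.3 at 50 to 99, 39.3 at 100 to 199 and 83.9 at 200 to 396. Of the 2508 sites that did not pass, 2191 had heights of 20 to 29. In that class 81.0% of sites were called higher in the ChIP library, against 99.6% of sites with heights of 100 to 199. Height itself followed the ChIP reads, and the median input count was 2 or 3 in each class, so the rise in ratio and in calls with height was set by the sorting.

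**Figure D2:**
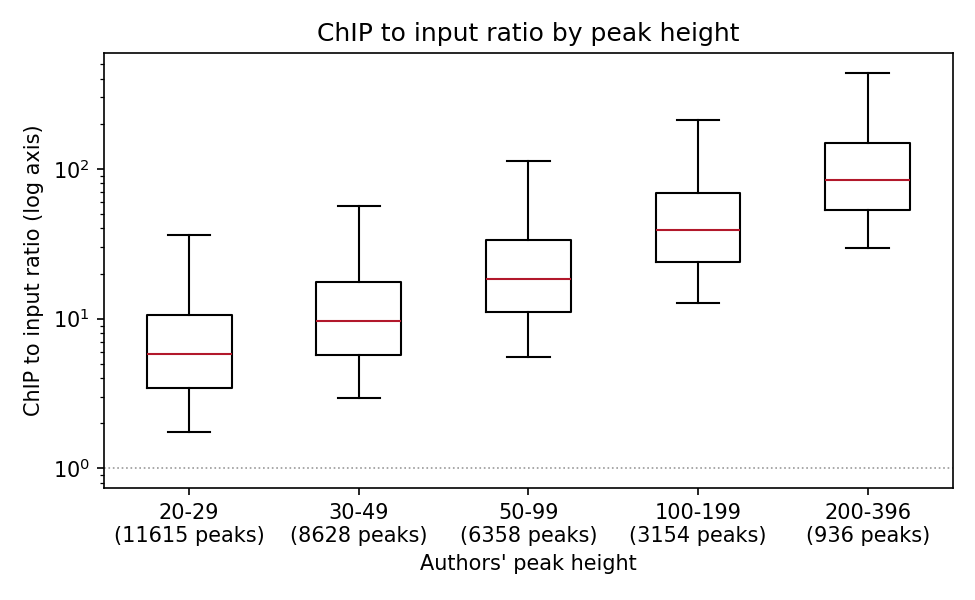
ChIP to input ratio per listed peak (log axis, 0.5 reads added to each count) by class of the authors' peak height. Boxes span the quartiles with the median in red, whiskers the 5th to 95th percentiles, and the dotted line marks equal density, with medians from 5.84 to 83.9, an order set by sorting on a height that follows ChIP reads.

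The highest peaks differed more in reads than in height. A window of 100 bp to each side has room for 402 combinations of position and strand, and heights followed the number of those in use (Spearman rho = 0.95 across peaks, which are not independent replicates). Their rank correlation with all reads in the window was nearly the same (rho = 0.94). The 131 peaks with heights of 300 or more had between 639 and 2679 ChIP reads in that window when all reads were counted. The highest peak of the list, at position 29762204 of chromosome 16, had a height of 396, 397 distinct reads and 2679 reads in all, against 6 input reads. Repeated reads were 30.3% of ChIP reads and 9.99% of input reads within 100 bp of listed positions.

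The 10 sites with the firmest excess over input lay on chromosomes 4, 10, 11, 13, 15, 16, 17 and 19. First was the span from 52228466 to 52228565 on chromosome 13, with 740 ChIP reads and 0 input reads, at least 254-fold higher when set against 3 reads. On chromosome 4 the span from 136454278 to 136454377 had 790 ChIP reads and 1 input read (ratio 814, exact 95% interval 146 to 32174), and the span from 83848294 to 83848393 had 757 and 1. The span from 17244256 to 17244355 on chromosome 19 had 516 ChIP reads and 0 input reads. All but few of the 573 ChIP reads within 100 bp of that position thus lay in the span, on its downstream side. The listed height there was 80, against 210 distinct ChIP reads within 100 bp. At 83848294 on chromosome 4 these values were 133 and 263, and they lay closer together at the rest of the 10. On chromosome 16 the span from 29762204 to 29762303 had 1562 ChIP reads and 5 input reads (ratio 322, 138 to 992), and the span from 80272939 to 80273038 had 433 and 0, at least 149-fold higher. The remaining members were the spans from 28698840 to 28698939 on chromosome 17 (761 ChIP reads and 1 input read), 107237769 to 107237868 on chromosome 11 (676 and 1), 119848206 to 119848305 on chromosome 10 (442 and 0) and 58875534 to 58875633 on chromosome 15 (663 and 1). The largest adjusted p among these 10 was 3.46e-131 (exact binomial test). All 10 were also called higher in the ChIP library under each alternative tried for them, but the size of the excess moved. It rested on few input reads. With 1 read per position and strand the ChIP counts also fell, as from 790 to 183 at 136454278 on chromosome 4, where the input count stayed at 1. With 5′ ends not moved, the chromosome 19 site had a ratio of 75.7 (298 ChIP and 4 input reads), under its bound of 177 from the span as listed. The ratio at 83848294 on chromosome 4 then went from 780 to 98.0, those on chromosomes 17, 11 and 15 from 784, 696 and 683 to 323, 189 and 154, and that at 29762204 on chromosome 16 from 322 to 933. Within 100 bp of the position, the chromosome 19 site had a ratio of 88.5 (573 and 7) and the chromosome 17 site 216. With 1 read per position and strand, which leaves room for at most 200 reads in a span, the 6 sites with input reads had ratios of 54.5 to 202, against 322 to 814 with all reads. The 4 sites without input reads were then at least 55.2-fold to 69.4-fold higher, against bounds of 149 to 254 with all reads.

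At the other end, 71 listed sites had significantly fewer ChIP than input reads, a number that fell to 19 with 1 read per position and strand and to 13 with the input density of the surrounding 10 kb. The lowest ratio was at 112058202 to 112058301 on chromosome 5, with 25 ChIP and 101 input reads (ratio 0.255, 0.158 to 0.398). It was followed by 79804390 to 79804489 on chromosome 15 (70 and 232 reads, ratio 0.311), 30754891 to 30754990 on chromosome 6 (13 and 40, ratio 0.335), 3008107 to 3008206 on chromosome 4 (31 and 94, ratio 0.340) and 3029462 to 3029561 on chromosome 11 (17 and 51, ratio 0.343). The chromosome 15 site did not pass with 1 read per position and strand (ratio 0.711, adjusted p = 0.317, exact binomial test). With that density in place of the peak's own input reads, the sites on chromosomes 5, 15 and 6 turned to ratios of 3.73, 12.4 and 6.93, past the threshold. The sites on chromosome 4 (ratio 1.04, adjusted p = 0.946) and chromosome 11 (ratio 0.655, adjusted p = 0.0630) then did not pass (exact binomial test). The median input count in the surrounding 10 kb, leaving out reads within 100 bp of the position, was 2418 at these 71 sites and 166 at the other 30620. The 71 were selected for their input reads, so this contrast was in part set by the selection and was not tested. Of the 71, 44 lay in the first 3.3 Mb of a chromosome, where mouse chromosomes carry their centromere, as did 149 of the other 30620. A single group of 103 listed peaks on chromosome 11, from 3023883 to 3102470, supplied a large part of the peaks counted there. The contrast is therefore not shown to hold across chromosomes.

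The next comparison was of the placement of sites along the genome. Listed Ptf1a sites lay closer together than random placements that follow input reads. Of the 30691 peaks, 18573 (60.5%) had a neighbour within 12.5 kb. Placements drawn at random in proportion to input reads gave a mean of 31.7% and at most 9948 such peaks in 100 draws. There were 766 groups of 5 or more peaks, and at most 71 in any random draw. Without the 1% of peaks with the most input reads around them, 18262 peaks (60.1%) had such a neighbour and 754 groups had 5 or more. The median distance between neighbouring peaks was 19921 bp, and 3701 neighbouring pairs lay within 1 kb, most often 200 to 399 bp apart (1390 pairs). Pairs under 200 bp apart numbered 135. Whether such close pairs are separate sites was not tested. The random placements kept only the number of peaks per chromosome and the input reads, so the contrast does not show why sites lay together.

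Groups were picked for mention after their values were seen. Read counts and ratios of a group cover its whole stretch, from the first listed position to the end of the last span, gaps between peaks included. They are thus not on the scale of the ratios of single sites given above. Among groups of 5 or more peaks, the greatest excess of ChIP reads was on chromosome 11 from 74277864 to 74369766. This stretch of 91.9 kb, with 25 peaks, held 8159 ChIP and 2687 input reads (ratio 3.13, exact 95% interval 2.99 to 3.27). The densest of the leading groups was on chromosome 5 from 30877367 to 30896842, with 9 peaks in 19.5 kb, 5478 ChIP and 665 input reads (ratio 8.48, 7.83 to 9.21) and a peak of height 383. Others lay on chromosome 5 from 36454344 to 36512871 (23 peaks, ratio 2.96), chromosome 9 from 70665418 to 70745586 (17 peaks, ratio 2.95) and chromosome 1 from 195208233 to 195275564 (22 peaks, ratio 2.86). The stretch of the group with the most peaks, 103 on chromosome 11 from 3023883 to 3102470, showed no excess over input (ratio 0.923, 0.907 to 0.940). Likewise the stretch with 49 peaks on chromosome 1 from 90108588 to 90184685 had a ratio of 0.870 (0.841 to 0.900). These 2 ratios do not show that the peaks themselves lay below input. The next groups by number of peaks lay above input, with 35 peaks on chromosome X from 166412531 to 166446738 (ratio 1.40, 1.34 to 1.47), 26 on chromosome 15 from 73537028 to 73591690 (ratio 2.22, 2.10 to 2.33) and 26 on chromosome 19 from 7164982 to 7261889 (ratio 1.99, 1.90 to 2.09).

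**Figure D3:**
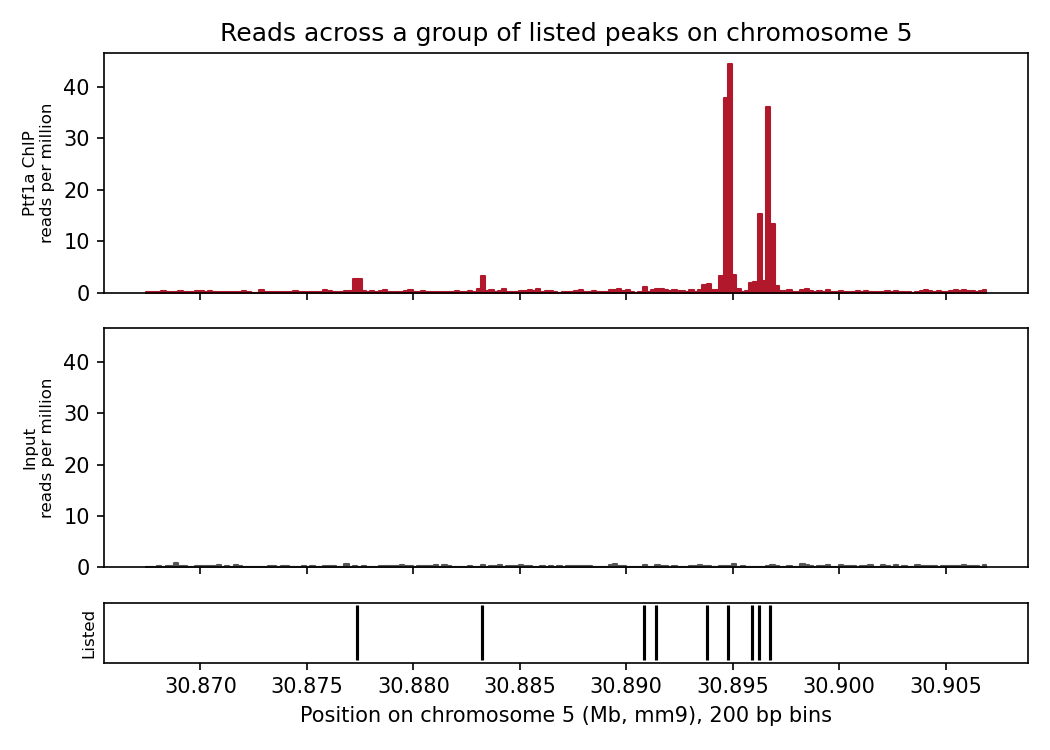
ChIP and input RPM in 200 bp bins, on the same scale, across the group of 9 listed peaks on chromosome 5 (mm9) with 10 kb to each side, and the listed positions as black lines. The ChIP library reaches 44.3 RPM in a bin, and the input library stays at or below 0.858.

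Chromosomes differed in their number of sites. Peaks per covered Mb ranged over the autosomes from 8.96 on chromosome 13 (95% counting interval 8.41 to 9.53) to 21.2 on chromosome 11 (20.4 to 22.1), with 19.6 on chromosome 15, 18.7 on chromosome 5, 17.3 on chromosome 19 and 16.9 on chromosome 4. Chromosome X had 364 peaks, or 2.59 per Mb (2.33 to 2.86). Of these, 35 lay in the 34.2 kb group named above, which held 3214 input reads. The autosomes had 13.2 peaks per Mb, a 5.10-fold difference (4.60 to 5.67). Read depth differed in the same direction. Input reads per Mb were 16564 on chromosome 15, 16168 on chromosome 5, 14631 on chromosome 11 and 8750 on chromosome 13, and the autosomal mean of 11893 was 2.76 times the 4304 on chromosome X. Across the 19 autosomes, peaks per Mb followed input reads per Mb (Pearson r = 0.90, Spearman rho = 0.93, each with a two-sided permutation p = 1e-05, adjusted 2e-05 over the 4 p-values of 2 relations, the smallest p that 100000 permutations can give). Without chromosomes 5 and 15, the farthest from the median in input reads, r was 0.87 and rho 0.90. The median height was 35 on chromosome X and 36 on the autosomes, and the median ratio of ChIP to input was 18.9 on chromosome X and 10.9 on the autosomes. With like heights, fewer input reads raise this ratio by construction. It was 15.8 on chromosome 13 and 7.80 on chromosome 15, the autosomes with the fewest and the most input reads per Mb. The ratio thus does not show stronger binding on chromosome X.

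**Figure D4:**
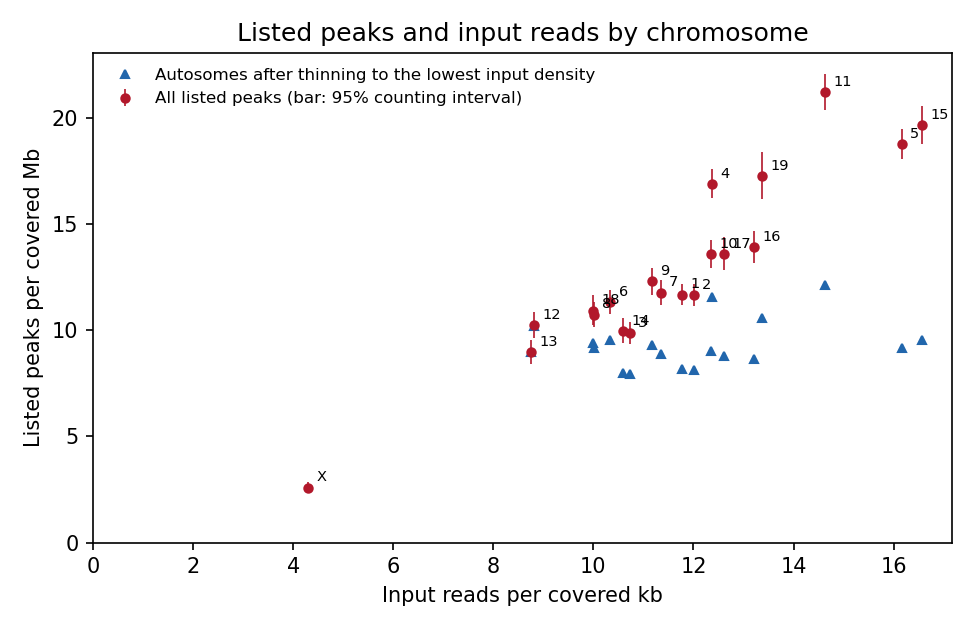
Listed peaks per covered Mb against input reads per covered kb for each chromosome, with 95% counting intervals (red circles, labelled by chromosome), and for the autosomes after heights were thinned to the lowest input density (blue triangles). Red points run from 2.59 on chromosome X to 21.2 on chromosome 11, and the triangles lie between 7.93 and 12.1.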

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

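The counting-noise test was written down before its result was seen, and the other tests of this part were chosen afterwards. The list covered most strong signal: of 13459 summits with 50 or more distinct ChIP reads and over 4 times the input, 93.7% lay within 250 bp of a listed peak and 5.71% (769) lay more than 1 kb away. At 100 or more distinct reads, 223 of 5574 lay that far. A scan of the whole genome found signal outside the list: of 30462 regions with more ChIP than input reads, 6750 lay more than 1 kb from any listed peak, and 3799 of these reached at least 20 distinct reads in a 200 bp bin, a number equal to the lowest height in the list. The strongest lay on chromosome 15 from 95676400 to 95676999, with 318 distinct ChIP reads in its highest bin and 560 ChIP against 34 input reads in all its passing bins. Others were on chromosome 15 from 39103400 to 39103799 (253 in the highest bin, 287 ChIP and 15 input reads), chromosome 3 from 27992800 to 27993399 (248, with 332 and 16) and chromosome 5 from 147507200 to 147507599 (248, with 278 and 15). The scan also met 25723 (83.8%) of the listed peaks.

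The same scan with the libraries exchanged gave 9 such regions against 6750, which met the bound written beforehand for a cause other than counting noise. The p-values were adjusted separately in each direction. With 12 passing bins against 47099, the p cutoff of the exchanged scan was stricter. Its 9 regions thus do not give the number of noise regions among the 6750, and the comparison does not decide what part of them is noise. A filter on repeated reads or strand balance is argued against as the whole cause. Of the 769 unlisted summits, 78.5% lay within the central 90% of listed summits of like height in both measures, against 81.0% of the listed summits. The bound used was 50%, and one of 80%, tried first, was dropped because the listed summits themselves barely reach it. Removal of sites with many input reads is argued against as the whole cause for these summits. The median input count in the surrounding 10 kb was 142 for unlisted and 170 for listed summits (one-sided permutation p = 0.0001), and the mean number of distinct input reads within 100 bp was 4.73 against 5.39 at listed summits of like height (two-sided permutation p = 0.0001), each the smallest p that 10000 permutations can give. Sites with less than 4 times the input were outside these tests. What set these sites apart stays open, other filters and a list used here only in part included, and no biological explanation was tested.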

How the results depend on the processing

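Changes of setting moved the amounts and left ChIP above input in the share of reads in peaks, the count of sites and the central to flank ratio. The share of ChIP reads in peaks, 5.10%, was 3.96% with 1 read per position and strand, 3.77% with 5′ ends not moved, 4.97% with reads moved 100 bp, 4.10% for the 15009 peaks above the median height and 9.98% in the window of 100 bp to each side. Fewer reads, fewer peaks or another window enter these values by construction, and the ratio to the input share ran from 10.8 to 20.2. The count of sites with more ChIP than input reads, 28112, fell to 14836 for the peaks above the median height, where only 15009 were tested. It was within 1.5 times of 28112 under the other alternatives, from 25154 with 5′ ends not moved to 30511 with the input density of 10 kb, and was 25852 with a ratio above 4 required. The count of sites with fewer ChIP reads, 71, was 19 with 1 read per position and strand, 13 with the input density of 10 kb, 42 among the peaks above the median height and between 61 and 86 under the others. The central to flank ratio of 16.6 was 13.8 with 1 read per position and strand and 27.6 for isolated peaks with no listed neighbour within 3 kb. The flanks of isolated peaks hold no listed neighbour by construction. Their ChIP flanks held 0.538 RPM per kb, against 0.977 for all peaks, and their centres 14.9 against 16.3. Whether anything else added to the change was not tested. With the input density of 10 kb in place of the peak's own, 3 of the 5 lowest sites reversed past the threshold, to ratios of 3.73 (chromosome 5), 12.4 (chromosome 15) and 6.93 (chromosome 6), and the chromosome 4 site lost its call at a ratio of 1.04 (adjusted p = 0.946, exact binomial test). In that order their spans held 101, 232, 40 and 94 input reads, against 7.03, 5.85, 2.00 and 31.2 expected from the 10 kb. Of all values of the 15 named sites under other settings, 109 kept their direction and side of the threshold. Besides the 4 just given, calls were lost for the chromosome 15 site with 1 read per position and strand (0.711) and for the chromosome 11 site with 5′ ends not moved (0.621) and with the input density of 10 kb (0.655). The ratios of the 10 highest sites kept their direction but moved in size, bounds for sites without input reads included. They lay between 149 and 814 as reported, 54.5 and 202 with 1 read per position and strand, 75.7 and 933 with 5′ ends not moved, 134 and 796 with reads moved 100 bp, and 88.5 and 887 in the window of 100 bp to each side. With the input density of 10 kb in place of the peak's own, and 0.5 reads added to each count, they lay between 262 and 772. The window of 100 bp and the isolated peaks were chosen after seeing the data. The alternatives for gene lists, peak position relative to genes and sequence motifs were not run, because gene positions and sequence of mm9 were not used here. No paired analysis was possible because each group held 1 library. With a median of 2 input reads per site, a site that did not pass is not shown to lack binding.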

Other observations

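The tests of read depth were written down before their results were seen, and the test of the input excess was chosen afterwards.

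Peaks per Mb rose with input reads per Mb, and chromosome X had the fewest of both. If depth were the cause, thinning each autosome's peak heights to the lowest autosomal input density should bring Spearman's rho below 0.3 with p above the threshold. After thinning, rho was 0.18 (two-sided permutation p = 0.448, adjusted 0.448) and Pearson's r 0.26 (p = 0.285, adjusted 0.379), or 0.36 without chromosomes 5 and 15. Differences in depth may thus account for the relation. Thinning takes more peaks from deeper autosomes by construction, however, so rho would fall whatever the cause. The test therefore does not show that depth was the cause. Chromosomes 11 and 4 then had the most peaks per Mb, 12.1 and 11.6, and chromosomes 15 and 5 fell to 9.54 and 9.17. For chromosome X, all autosomal heights were thinned by the same mean depth ratio. This left 9528 autosomal peaks and a ratio of 1.60 (exact 95% interval 1.44 to 1.79, counting error only). If depth were the cause, the interval should include 1, and it did not. Depth may account for much of the 5.10-fold difference, though thinning lowers this difference by construction too. Whether it accounts for the whole is not decided. The interval treats grouped peaks as independent and leaves out spread between chromosomes. A single factor thins the deepest autosomes too little and the shallowest too much. Of the 364 peaks on chromosome X, 35 lay in a single group, and counting them lowers the ratio. Whether the depths reflect chromosome copies in this line or sequence composition was not tested, and no biological explanation was tested.

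Input reads were also denser at listed positions, at 1.54 to 1.70 times the density of the surrounding 10 kb in each of 10 classes of peak height, leaving out 303 peaks with more than 31 input reads. Immunoprecipitated DNA in the input library would add input reads as a fixed share of the ChIP excess. That share was 9.06% in the lowest class (bootstrap 95% interval 8.48 to 9.65%) and 0.703% in the highest (0.669 to 0.736%), which argues against such carry-over as the whole cause. The input excess per site was 2.14 reads in the lowest class, 1.97 in the ninth and 2.64 in the highest. Chromatin that breaks or is recovered more readily at bound sites is a candidate explanation that stays open, since no measure of it was analysed here.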
